A study of Mus musculus with 74 samples.

How the data were processed

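The deposited table held 379042 entries from 74 mice, and 378754 of them were tumours, each given by its mouse, its 2 guides, its reads and its estimated cells. Per the labels, lungs were harvested about 3 months after tumours were started, and barcode and guides were amplified together from 32 µg of lung DNA and sequenced, with 1 library per mouse. The deposited read column holds counts, the reads of each tumour without normalization. The deposited cell column holds a signal, the cells of each tumour estimated by the authors with spike-in barcodes. Within each mouse the cells were the reads times 1 factor, checked on the values. The factor put the 3 main spike-in entries of a mouse at a total near 100000 cells (5 KT and 25 H11-Cas9 mice) or near 300000 cells (4 KT, 20 H11-Cas9 and 20 H11-LSL-Cas9 mice). The smallest tumour listed had 50.1 cells and 3 reads, so smaller ones cannot be seen here, and steps before the table are not given in the sources used here. The median number of cells behind 1 read was 4.82 in KT, 7.96 in H11-Cas9 and 12.9 in H11-LSL-Cas9, so the smallest tumours of that group were coarse estimates. The spike-in total was kept as a possible batch because it splits the groups unevenly. The letters that begin the mouse names in the labels, whose meaning is not given in the sources used here, were another: SL (5 KT mice, total near 100000), LA (4 KT and 14 H11-Cas9 mice near 300000 and 25 H11-Cas9 near 100000), CM (6 H11-Cas9), and HC (15) or MT (5) in H11-LSL-Cas9.

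Groups came from the genotype given for each mouse: KT (9 mice without Cas9), H11-Cas9 (45) and H11-LSL-Cas9 (20). Viral dose is not given in the sources used here. Guides were assigned to 17 genes by name, 10 with 2 guides and 7 with 1, with Lkb1 read as Stk11 and p53 as Trp53. The 5 guides named safe (3 guides), NT and EGFP were taken as inert and served as the controls. The guide named NE was counted neither as inert nor as targeting. There were 33 guides in place 1 and 32 in place 2, since Meaf6 was in place 1 alone. The entries of spike-ins (287), 1 entry with a spike-in in place of a guide, and, for the values reported, 6757 tumours on constructs with the same guide in both places were left out.

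Size effects were computed within each mouse as the mean log2 cells of a genotype minus that of inert/inert tumours, both orders and all guides of a gene together, for mice with at least 5 tumours of each kind. The mean and standard error over mice were tested by 2-sided sign flips, exact where the mice allowed and otherwise with 100000 resamples, and adjusted over all genotypes of a kind by the Benjamini-Hochberg method, with a call at an adjusted p under 0.05. An interaction was the effect of a pair minus the sum of its single effects in the same mouse. A step was the difference between a pair and each of its single genes, or between a gene and inert/inert, with all first and second steps adjusted together, and a path of adding a gene and then another was open when neither step passed as a decrease. Number effects were the mean over mice of log2 of the tumours of a genotype plus 0.5 over the inert/inert tumours plus 0.5, Cas9 minus KT mice, tested by permuting mouse labels 100000 times, and for tumours of all sizes mice with at least 5 inert/inert tumours entered. Ratios of summed numbers (1000 bootstraps of mice) and of percentiles (300 bootstraps) have 95% intervals. Differences from KT in size used the studentised permutation. The 2 Cas9 groups were compared by permuting mouse labels, and guide choice and order by sign flips within mice. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

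The tests, a minimum of 1000 cells, the alternatives and the rule for naming genes were fixed before the data were examined. Settings fixed as alternatives were a minimum of 500 or 2000 cells or none, the 90th percentile, at least 10 tumours, adaptive sampling (the largest tumours of a genotype, as many as its share in KT times 50% of the inert/inert number), mice weighted by tumours, both Cas9 groups together and other size scales. For number they were a pseudocount of 1, number relative to all tumours, summed numbers, and leaving out each KT mouse. After the data were seen, the planned setting of all sizes was taken for the values reported, since 1000 cells left few tumours. The removal of same-guide constructs, a minimum of 200 cells, the studentised permutation, the separation by spike-in total and by mouse names, and the counting of NE as inert were added. So were leaving out the H11-LSL-Cas9 mice of under 20 tumours (mice 3 and 7) from tumour number and burden, and counting paths with first steps adjusted over single genes. The naming rule took all genes beside an inert guide, and of pairs the 8 largest and 5 smallest size effects past the threshold, the 8 most positive and 8 most negative interactions in size and the 5 and 5 in number. Some results are not reported here, and are left out of the figures too, while counts cover all genes tested. Pairs named in the comparison of the Cas9 groups, in pair numbers, steps and in guide order were chosen after their values were seen.

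The tests were tested on simulated data in 3 simulations that kept the tumours per mouse. Sizes were drawn within the mouse and constructs by their share in KT, and known effects were added in Cas9 mice. All mice of a group drew constructs from the same shares, so these varied between mice by sampling alone. Tumours shifted below the smallest size listed were kept. The rates given here may therefore be better than those in the real data. In H11-Cas9, a true size effect of 0.25 log2 units was called for 9 of 12 single genes and an effect of 0.5 for 6 of 6, and 2 of 27 unchanged genes were called. A true interaction of 0.5 was called in 13 of 24 pairs, -0.5 in 14 of 23 and -0.25 in 2 of 26, with 1 of 245 false calls. In H11-LSL-Cas9 the size effects of 0.25 and 0.5 were called for 4 of 12 and 4 of 6 single genes, and interactions of 0.5 and -0.5 for 6 of 24 and 6 of 21 pairs, with 0 of 250 false calls by the sign-flip test. Number effects of -1 were called for 6 of 6 single genes in H11-Cas9, while 11 of 110 unchanged pairs were called. That is a share of the unchanged pairs. The adjusted p bounds the share of false calls among all calls, which depends also on how many pairs truly change. Number interactions of 1 and -1 were called in 23 of 30 and 14 of 30 pairs, with 9 of 318 false calls.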

Results

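The lungs of 74 mice were analysed, harvested about 3 months after tumours had been started with a lentiviral pool in which each virus carried Cre, a tumour barcode and a pair of guide RNAs. All mice had the background that the labels call KT, with a Tomato reporter. Of these, 9 KT mice had no Cas9, so that their guides could not cut, 45 carried H11-Cas9, and 20 carried H11-LSL-Cas9, in which Cre must remove a stop cassette before Cas9 is made. The guides targeted 17 genes, and 5 inert guides served as controls, so that 136 gene pairs were possible beside the single genes paired with an inert guide. The table listed 378754 tumours with the reads and the estimated cells of each. A KT mouse held 23234 ± 8687 tumours (mean ± SD, n = 9, from 13191 to 41166), an H11-Cas9 mouse 2663 ± 822 (n = 45, from 1013 to 5364) and an H11-LSL-Cas9 mouse 2490 ± 1332 (n = 20, from 4 to 4941). Reads per mouse ranged from 1.43e+06 to 1.12e+07 in KT, from 118601 to 6.26e+06 in H11-Cas9 and from 37 to 1.16e+06 in H11-LSL-Cas9, and the median number of cells behind 1 read was 4.82, 7.96 and 12.9. Mice were the replicates throughout. With 9 KT mice an exact sign-flip test cannot give a p below 0.00391.

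Before any gene is considered, the groups differed in tumour number. Among tumours of at least 1000 cells, the mean log2 number per mouse was lower in H11-Cas9 than in KT (difference -3.86, 45 against 9 mice, permutation p = 1e-05, the smallest the permutations can give). It was lower in H11-LSL-Cas9 too (-4.98, 20 against 9 mice, permutation p = 1e-05). That mean is pulled down by mouse 7 (4 tumours, 0 of at least 1000 cells) and mouse 3 (16 tumours, 1 of that size). Without both the difference was -4.20 (18 against 9 mice, permutation p = 1e-05), and without mouse 7 alone -4.57. Within mice that shared a spike-in total, the H11-Cas9 difference was -4.10 near 100000 cells and -3.55 near 300000 cells, and the H11-LSL-Cas9 difference was -4.89 near 300000 cells. Summed tumour cells of these tumours did not pass (differences -0.47, permutation p = 0.307, and -2.09, permutation p = 0.0664), although without these 2 mice H11-LSL-Cas9 did at -1.09 (permutation, adjusted p = 0.0379). The size of tumours with 2 inert guides did not pass either (differences 0.26 and 0.02, permutation p = 0.322 and 0.922). With tumours of all sizes counted, summed cells were lower in both Cas9 groups (-1.14 and -2.71, permutation p = 0.00732 and 0.0186), and so was the size of inert/inert tumours (-0.71 and -0.56, permutation p = 6e-05 and 0.0364). For summed cells of H11-LSL-Cas9 the difference was -2.15 without mouse 7 and -1.71 without both (permutation, adjusted p = 0.00315 and 0.000135). Near 300000 cells, against 4 KT mice, summed cells of all sizes did not pass (-0.93 and -2.73, permutation p = 0.151 and 0.0811). Inert/inert size there passed in H11-Cas9 (-0.68, permutation p = 0.0166) but not in H11-LSL-Cas9 (-0.63, permutation p = 0.0913). Near 100000 cells both passed in H11-Cas9 (-1.31 and -0.74, permutation p = 0.0235 and 0.0006). The names of all 20 H11-LSL-Cas9 mice in the labels begin with letters (HC or MT) that no KT or H11-Cas9 mouse has, so a batch marked by them cannot be told apart from that genotype. Among H11-Cas9 and KT mice that share the letters LA and the total near 300000 cells, the number difference was -3.61 (14 against 4 mice, permutation p = 0.00035). The viral dose of a mouse is not given in the sources used here, so these differences describe the mice and not the effect of Cas9.

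The size setting fixed before the data were examined, tumours of at least 1000 cells with at least 5 per genotype and mouse, left little to test, because an H11-Cas9 mouse held 1.87 inert/inert tumours of that size on average. In it 6 single genes could be tested over at most 3 H11-Cas9 mice, where an exact test cannot go below 0.25, and 0 passed the sign-flip permutation test (0 at an unadjusted p under 0.05). Nf1 and Rasa1 lay at 1.0003 ± 0.17 and 0.26 ± 0.19 log2 units above inert/inert there (mean ± SE, 3 mice each, exact p = 0.25). Of 17 gene pairs and 11 interactions testable in H11-Cas9, 0 passed in either (0 at an unadjusted p under 0.05), and in H11-LSL-Cas9 no genotype had more than 1 mouse. The size results below therefore come from tumours of all sizes, an alternative planned beforehand, without constructs that held the same guide in both places, a choice made after the data were seen and taken from KT mice alone.

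In KT mice, where no cutting can occur, single genes lay between -0.14 (Meaf6) and 0.14 (Kmt2a) log2 units of inert/inert, and 0 of 17 passed the exact sign-flip permutation test after Benjamini-Hochberg adjustment (2 at an unadjusted p under 0.05, Keap1 at 0.09 and Pcna at 0.10). Of 134 gene pairs 0 passed (5 unadjusted), and of 134 interactions 0 passed (7 unadjusted). With the same-guide constructs kept, 3 of 17 single genes passed in KT, all above inert/inert.

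Targeting 1 gene enlarged tumours for 11 of 17 genes in H11-Cas9 mice and shrank them for 1. Tumours with a guide against Nf1, a RAS-inactivating protein, were 1.35-fold the size of inert/inert tumours (log2 0.43 ± 0.06, mean ± SE, 45 mice). Those against the tumour suppressor p53 were 1.22-fold (0.29 ± 0.05) and those against Rasa1, another RAS-inactivating protein, 1.19-fold (0.25 ± 0.04). Each of these 3 had an adjusted p of 4.25e-05 in the sign-flip permutation test, and the size was above inert/inert in 40 of 45 mice for Nf1, 38 for p53 and 37 for Rasa1. Pcna, the sliding clamp of DNA replication, had tumours of 0.743-fold size (-0.43 ± 0.16, 13 mice, 11 of them below 0, adjusted p = 0.0374), and it did not pass with same-guide constructs kept (-0.36, adjusted p = 0.0605) or among mice whose names in the labels begin with LA (-0.37, adjusted p = 0.12).

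By the lists fixed beforehand, both RAS and MAPK genes rose (Nf1, Rasa1). So did both of the p53 and cell cycle list (p53 and Rb1, the brake on cell cycle entry, at 0.15 ± 0.05), and the kinase Lkb1 rose by 0.27 ± 0.09 (adjusted p = 0.00909). The histone methyltransferase Setd2 rose by 0.22 ± 0.05, the Wnt pathway scaffold Apc by 0.16 ± 0.07 (adjusted p = 0.0367) and the ubiquitin ligase Rnf43 by 0.15 ± 0.05. Keap1, the adaptor that targets NRF2 for degradation, lay at 0.04 ± 0.07 (adjusted p = 0.636). Of the 6 genes in no list, 2 rose, the cyclins Ccnl1 (0.27 ± 0.08, 43 mice) and Ccnl2 (0.17 ± 0.07, 44 mice), and adjusted over the list alone 1 did. Kat7 (0.21 ± 0.11), Meaf6 (0.25 ± 0.21, 13 mice), Kmt2a (0.08 ± 0.07) and Kmt2b (-0.00 ± 0.12) did not pass. The counts of the other lists were the same when adjusted over the list alone. Lkb1 tumours had a median of 0.914-fold that of inert/inert and a 95th percentile of 6.72-fold (95% interval 2.44 to 15.7, mice resampled), against 2.24-fold for Nf1. Among tumours of at least 200 cells Lkb1 lay at 0.88 ± 0.15 (36 mice) and Keap1 passed (0.23, adjusted p = 0.0155), while Ccnl1 (0.31, adjusted p = 0.0652) and Ccnl2 (0.04, adjusted p = 0.694) did not. Adaptive sampling, which keeps the largest tumours in proportion to what the virus pool supplies and so joins number with size, turned Lkb1 (-0.61), Apc (-0.47) and Setd2 (-0.01) below 0 and gave Keap1 -0.81. Set against KT mice by permutation of the difference over its standard error, Nf1 (0.46), p53 (0.28) and Rasa1 (0.21) stayed above and Pcna (-0.53) below, and 7 calls were lost. Among mice with a spike-in total near 100000 cells 12 of 17 genes passed, and among those near 300000 cells 5 did. There Apc lay at -0.00, Lkb1 at 0.04, Rb1 at 0.04, Ccnl2 at 0.06, Rnf43 at 0.08, Ccnl1 at 0.23 and Pcna at -0.39, with adjusted p from 0.235 to 0.952, against 0.29, 0.45, 0.25, 0.26, 0.20, 0.31 and -0.57 near 100000 cells, where all but Pcna passed. Nf1, p53, Rasa1 and Setd2 passed near both totals.

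In H11-LSL-Cas9 mice Pcna tumours were 0.803-fold the size of inert/inert (-0.32 ± 0.10, 15 of 16 mice below, adjusted p = 0.0436), and Pcna passed against KT mice too. It did not pass with same-guide constructs kept (-0.24, adjusted p = 0.223), nor among tumours of at least 200 cells (-0.06 ± 0.21, 9 mice, exact test, adjusted p = 0.842). Nf1 lay at 0.11 ± 0.10 and p53 at 0.08 ± 0.08, and Kmt2b, a histone methyltransferase, at 0.39 ± 0.16 (13 mice, adjusted p = 0.216). The guide named NE, which was treated as neither inert nor targeting, lay at 0.00 ± 0.04 in H11-Cas9 and -0.10 ± 0.07 in H11-LSL-Cas9. Its tumour number over inert/inert, against KT mice, lay at -0.08 ± 0.08 and -0.26 ± 0.12 (permutation p = 0.597 and 0.1).

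**Figure D1:**
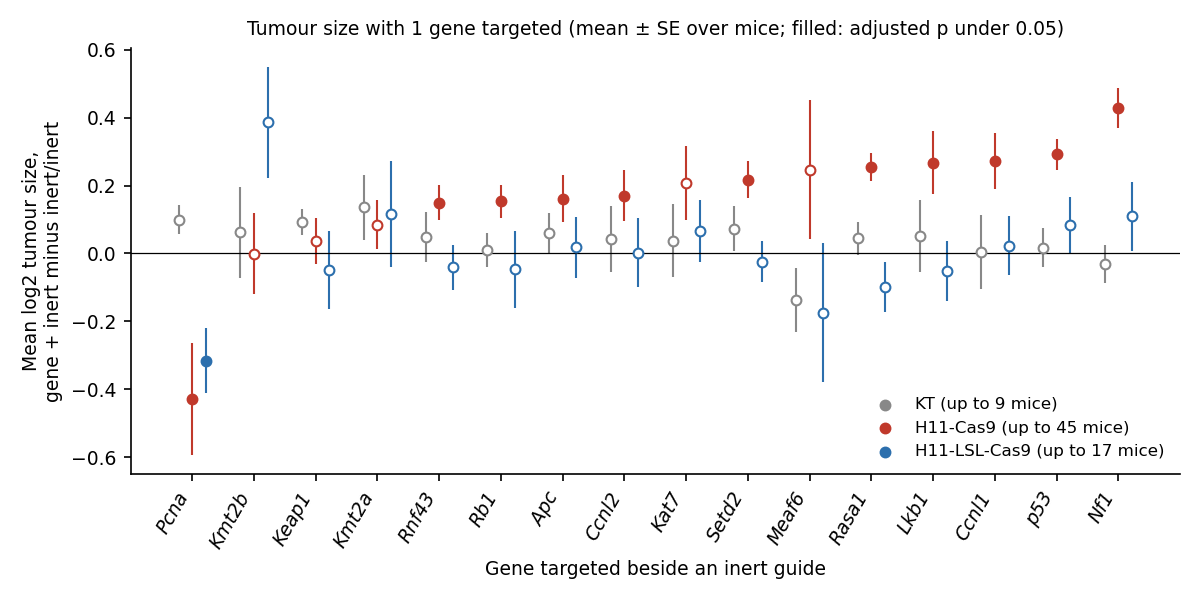
Mean log2 tumour size of genes paired with an inert guide, minus inert/inert tumours of the same mouse, with standard errors over mice for KT, H11-Cas9 and H11-LSL-Cas9; filled points passed at an adjusted p under 0.05. Nf1 reached 0.43 and p53 0.29 in H11-Cas9, Pcna lay at -0.43, and no KT point passed.

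Most changes in tumour number were decreases. Relative to inert/inert and to KT mice, the number of tumours with a guide against Pcna fell to 0.0558-fold in H11-Cas9 (log2 -4.16 ± 0.14, 45 against 9 mice, 190 against 4256 tumours), with Lkb1 to 0.440-fold (-1.19 ± 0.09), and with Kmt2b to 0.479-fold (-1.06 ± 0.12). Keap1 tumours fell to 0.509-fold (-0.97 ± 0.07), those with Apc to 0.629-fold (-0.67 ± 0.07) and those with Setd2 to 0.803-fold (-0.32 ± 0.06). Tumours with Nf1 were more numerous, 1.33-fold (0.41 ± 0.07). The label permutation with Benjamini-Hochberg adjustment thus called 1 gene up and 6 down of 17, with adjusted p from 5.67e-05 for Pcna to 0.0382 for Setd2. Nf1 and Setd2 were no longer called without KT replicate 2, 3, 5, 6, 7 or 8, nor Setd2 without KT replicate 4 (adjusted p from 0.0502 to 0.0762). Kat7, an acetyltransferase, at -0.55 ± 0.13 (permutation, adjusted p = 0.0619) and Meaf6 at -0.58 ± 0.16 (0.0964) did not pass. By list, 1 of 2 RAS and MAPK genes rose. Of the p53 list 0 of 2 genes passed (p53 at 0.22 and Rb1 at -0.05, 0 at an unadjusted p under 0.05), and Keap1 of the ubiquitin and NRF2 list fell. Permutation of the difference over its standard error called 13 of 17. Among them were Kat7 (adjusted p = 0.000623), p53 (0.00456) and Meaf6 (0.00704), beside Nf1 (0.000227) and Setd2 (0.000276), but not Rb1 (0.441).

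In H11-LSL-Cas9 (17 against 9 mice), Pcna fell to 0.308-fold (-1.70 ± 0.16), Keap1 to 0.718-fold (-0.48 ± 0.10) and Lkb1 to 0.765-fold (-0.39 ± 0.10), each by permutation, with adjusted p of 0.00017, 0.0181 and 0.0344. These 3 falls were shared with the 6 of H11-Cas9. Leaving out KT replicate 1, 4, 6, 7 or 8 left 2 falls. At the setting of at least 1000 cells the split turned, with 6 genes up and 1 down in H11-Cas9, among them Meaf6 1.56, Nf1 1.37, Ccnl1 1.34, Rasa1 0.92, p53 0.89 and Pcna -2.99. It was 5 up and 1 down in H11-LSL-Cas9, among them Meaf6 2.14, Ccnl1 1.496, Kat7 1.48, Kmt2a 1.41 and Pcna -1.62. That setting counts growth past 1000 cells together with number, and its inert/inert counts were low enough for the pseudocount of 0.5 to matter. From summed tumours Meaf6 lay at 0.24 and Ccnl1 at 0.82 in H11-Cas9. Numbers over tumours of all sizes also count only tumours past the smallest size listed in a mouse. That size was 50.4 to 56.2 cells in KT, 50.1 to 105 in H11-Cas9 and 50.4 to 369 in H11-LSL-Cas9. They are therefore not fully separate from growth either.

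**Figure D2:**
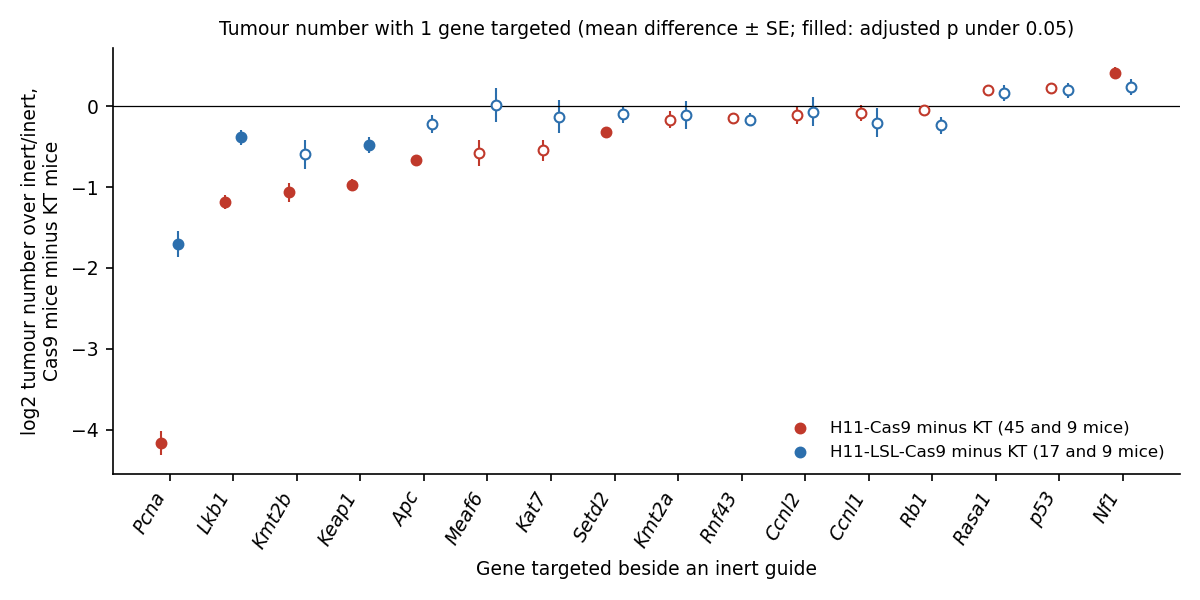
Mean log2 tumour number of genes over inert/inert, Cas9 mice minus KT mice, with standard errors for H11-Cas9 and H11-LSL-Cas9; filled points passed at an adjusted p under 0.05. Pcna lay at -4.16 and -1.70, and Lkb1, Keap1 and Apc lay lower in H11-Cas9 than in H11-LSL-Cas9.

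Of 106 gene pairs testable for size in H11-Cas9, 38 had larger and 1 had smaller tumours than inert/inert (48 at an unadjusted p under 0.05). Set against KT mice by permutation of the difference over its standard error, 21 of 104 pairs lay higher and 5 lower (38 unadjusted). Tumours with p53 and Rb1 both targeted were 1.91-fold the size of inert/inert (log2 0.93 ± 0.08, above in 45 of 45 mice), and their 95th percentile was 10.5-fold (95% interval 7.28 to 15.4). Large effects were also seen for Apc with Lkb1 (0.63 ± 0.22, 34 mice), Nf1 with p53 (0.54 ± 0.06) and Lkb1 with Setd2 (0.47 ± 0.15). Nf1 and Rasa1 were members of 9 of the larger pairs each, Lkb1 of 8 and p53 of 7. Small effects that passed were those of Apc with Rasa1 (0.21) and Lkb1 with Rnf43 (0.22). In H11-LSL-Cas9, 3 of 110 pairs were larger, all 3 among the larger pairs of H11-Cas9, and 1 was smaller (19 at an unadjusted p under 0.05). The smaller one was Apc with Pcna (-0.65 ± 0.12, below in 13 of 13 mice). Adaptive sampling turned Apc with Lkb1 (-0.26), Lkb1 with Setd2 (-0.38), Apc with Rasa1 (-0.06) and Lkb1 with Rnf43 (-0.63) below 0, and Lkb1 with Setd2 lay at -0.02 in mice with a spike-in total near 300000 cells.

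The series title names epistasis, so each pair was set against the product of its single effects. In H11-Cas9, 22 of 106 pairs had smaller tumours than that product and 1 had larger (35 at an unadjusted p under 0.05). The median over all 106 interactions was -0.21 log2 units, against -0.05 over 134 in KT mice. The larger one was p53 with Rb1, at 0.49 ± 0.09 log2 units above the sum of the single effects (36 of 45 mice above, adjusted p = 0.000353). It was 0.00 ± 0.07 without constructs with p53 in place 1 and the Rb1 guide V1 in place 2, which were chosen as the highest. Below it were Ccnl1 with Nf1 (-0.52 ± 0.15, 34 mice) and with p53 (-0.47 ± 0.14, 32 mice). Smaller deficits were those of Ccnl2 with Setd2 (-0.39 ± 0.12) and Keap1 with Nf1 (-0.36 ± 0.09). Nf1 was in 7 of the negative pairs, Keap1 and p53 in 5 each, and Rnf43 and Setd2 in 4 each, while Lkb1 was in 0 of its 15 tested pairs. Among tumours of at least 200 cells 16 pairs were below the product, 10 of them among these 22, and p53 with Rb1 was again the 1 above it.

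Every interaction uses the inert/inert tumours of the same mouse, so the 22 negative calls are not independent of each other. With the median of all 106 below 0, a shift common to the pairs was not told apart from effects of particular pairs. Against KT mice, 2 of 99 interactions passed by permutation (13 unadjusted), 1 higher and 1 lower than in KT, with a median of -0.17. The higher one was p53 with Rb1 at 0.47 ± 0.10 (permutation, adjusted p = 0.0361). Only 1 negative call was thus made against KT, where a simulated interaction of -0.5 was called in 7 of 22 pairs. Within the spike-in totals 12 (100000 cells, 0 above and 12 below) and 4 (300000 cells, 1 above and 3 below) passed. In H11-LSL-Cas9, 0 of 107 interactions passed the sign-flip permutation test (5 unadjusted), and in simulated data of that size a true interaction of 0.5 was called in 6 of 24 cases. Adaptive sampling gave 4 positive and 17 negative interactions of 83 in H11-Cas9, with Ccnl1 with p53 at 0.08 and Ccnl2 with Setd2 at 0.18.

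**Figure D3:**
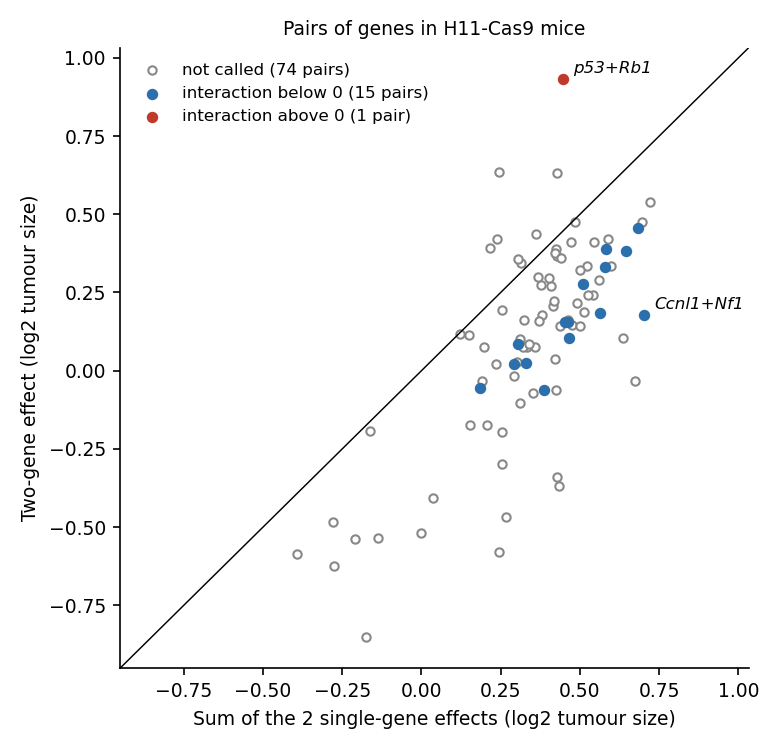
For 90 gene pairs in H11-Cas9, the mean log2 size of tumours with both genes targeted against the sum of the single-gene effects; the line marks equality. The 15 pairs called below the product of the single effects are filled in blue, among them Ccnl1 with Nf1, and p53 with Rb1 (red) is the pair called above it.

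For the accessibility that the title names, each pair was read as steps of adding a gene. Of 212 steps that added a second gene in H11-Cas9, 20 raised tumour size and 10 lowered it. Steps that raised size added, among others, Nf1 (6 steps, 0.16 to 0.26), p53 (4, 0.16 to 0.78), Rasa1 (3, 0.12 to 0.19), Rb1 (0.64) or Lkb1 (0.32). Steps that lowered it added Keap1 (5 steps, -0.32 to -0.20), Kmt2b (3, -0.73 to -0.55) or Pcna (for example -0.71 beside p53). A path, adding a gene and then another, had no step that lowered size in 202 of 212 cases (95.3%), and 0 genes raised size when added alone and lowered it when added to another gene. In H11-LSL-Cas9, 4 steps raised and 2 lowered size, among them Pcna added to Apc (-0.60), with 215 of 217 paths open (99.1%). Steps were adjusted over first and second steps together, where Pcna alone did not pass (adjusted p = 0.116 in H11-Cas9 and 0.1 in H11-LSL-Cas9). With Pcna counted as a first step that lowered size, as adjustment over single genes called it, 193 of 212 (91.0%) and 203 of 217 (93.5%) were open. A path counts as open where no step passed as a decrease, so few passing steps make many open paths, and at least 1000 cells gave 66 of 66 open in H11-Cas9. In H11-Cas9 106 of 136 pairs had enough tumours to be tested for size. Of 16 pairs each, 9 with Pcna, 9 with Kmt2b and 3 with Meaf6 were among them. Paths through pairs with few tumours are thus under-represented in these shares. Adaptive sampling called 36 steps up and 37 down of 182.

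Tumour number of pairs fell more often than it rose, with 64 down and 11 up of 136 in H11-Cas9 and 26 down and 7 up in H11-LSL-Cas9, of which 25 falls and 5 rises were shared. All 16 pairs with Pcna fell in H11-Cas9, from -4.50 ± 0.17 with Lkb1, -4.40 with Rb1 and -4.33 with Keap1. So did 16 of 16 with Keap1, 15 with Lkb1, 13 with Kmt2b, 10 with Setd2 and 8 with Apc. Among the pairs that rose were Nf1 with p53 1.498-fold (0.58 ± 0.07) and Nf1 with Rasa1 1.49-fold (0.58 ± 0.07). In H11-LSL-Cas9, Pcna fell in 15 pairs and Lkb1 in 8. At the setting of at least 1000 cells the split was 80 up and 10 down in H11-Cas9 and 84 up and 2 down in H11-LSL-Cas9.

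Of 136 interactions in number, 1 was negative in H11-Cas9, the related cyclins Ccnl1 with Ccnl2 (-1.50 ± 0.22, permutation, adjusted p = 0.00913, 28 against 182 tumours), and from summed numbers it lay at -2.06 (95% interval -2.73 to -1.53). The 9 positive calls rested on very few tumours, led by Meaf6 with Pcna (3.15 ± 0.27, 8 against 118 tumours), Kmt2b with Meaf6 (2.20), Kmt2b with Pcna (2.03), Ccnl1 with Meaf6 (1.87) and Kat7 with Pcna (1.81). From summed numbers these were 1.24, 1.20, 1.05, 0.16 and 0.37, and 0 of 136 interactions passed there by permutation (3 at an unadjusted p under 0.05). In H11-LSL-Cas9, 0 of 136 passed the permutation test (5 unadjusted). At the setting of at least 1000 cells, Ccnl1 with Ccnl2 lay at 0.07 in H11-Cas9 and 15 interactions were positive and 1 negative.

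The labels name both Cas9 alleles, and their effects were compared directly, although the names of their mice share no letters, so that the allele and a batch marked by the names cannot be told apart. Size effects were larger in H11-Cas9 for 5 of 115 genotypes and smaller for 0. These were Rasa1 (difference 0.35 ± 0.08, adjusted p = 0.00172), p53 with Rb1 (0.74 ± 0.14), Rasa1 with Setd2 (0.41 ± 0.10), Nf1 with p53 (0.34 ± 0.10) and p53 with Rasa1 (0.32 ± 0.10). Numbers were lower in H11-Cas9 for 65 of 153 genotypes and higher for 0, with Pcna at -2.47 ± 0.21, Lkb1 at -0.80 ± 0.12, Meaf6 at -0.59 ± 0.23, Keap1 at -0.50 ± 0.12, Kmt2b at -0.47 ± 0.19 and Apc at -0.45 ± 0.12. Among mice with a spike-in total near 300000 cells, the size difference passed for p53 with Rb1 alone (0.76 ± 0.15, 1 of 110 genotypes). Rasa1 lay at 0.29 ± 0.10 there (unadjusted p = 0.00363, adjusted 0.166), Rasa1 with Setd2 at 0.33 ± 0.11, Nf1 with p53 at 0.26 ± 0.12 and p53 with Rasa1 at 0.19 ± 0.10, with fewer mice. The number was lower for 44 genotypes and higher for 3, with Pcna at -2.02, Lkb1 at -0.70, Apc at -0.50 and Keap1 at -0.47, while Meaf6 (-0.35, adjusted p = 0.379) and Kmt2b (-0.23, adjusted p = 0.408) did not pass.

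**Figure D4:**
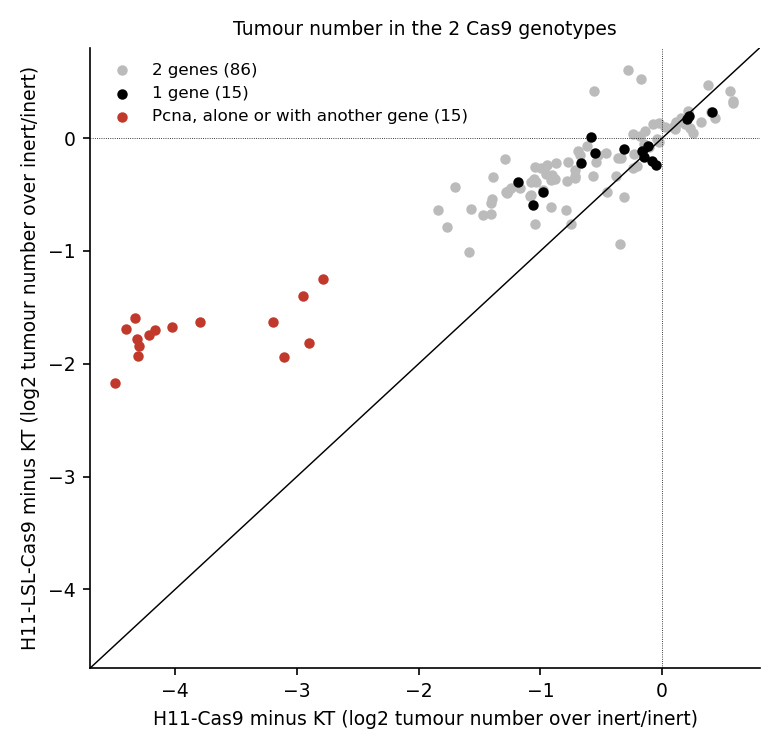
Log2 tumour number over inert/inert, each Cas9 group minus KT, with H11-Cas9 on the horizontal and H11-LSL-Cas9 on the vertical axis, for 116 genotypes with at least 200 tumours in H11-Cas9 and KT together; the line marks equality. The 15 genotypes with Pcna (red) lie farthest below 0 on both axes and above the line.

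Guide choice and guide order were compared within mice. In KT the guides of 0 of 10 genes differed by the exact sign-flip test (0 unadjusted), while those of 1 of 10 differed in H11-Cas9 and of 1 of 10 in H11-LSL-Cas9. Order mattered for 2 of 78 pairs in H11-Cas9. Tumours with Rb1 in place 1 and p53 in place 2 were smaller than those in the reverse order (-0.71 ± 0.10, 43 mice), and so were those with Rnf43 before p53 (-0.26 ± 0.07). In H11-LSL-Cas9, 3 of 85 passed (Lkb1 before Setd2 0.93, Keap1 before Lkb1 0.29, Rasa1 before p53 -0.44), and in KT 0 of 130 passed the exact test (7 unadjusted). For p53 with Rb1 the excess over the single effects lay in constructs with p53 in place 1 and the Rb1 guide V1 in place 2 (1.28 ± 0.14, 44 mice, 769 tumours, permutation p = 1e-05, the smallest the permutations can give). Without them the interaction was 0.00 ± 0.07 (45 mice, p = 0.953), and in KT that construct lay at -0.10 ± 0.09 (exact p = 0.27, 9 mice). These constructs are the 2 highest of 8 arrangements in the same H11-Cas9 mice. Their p-value and the value without them are therefore shaped by that choice, which is examined further below.

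**Figure D5:**
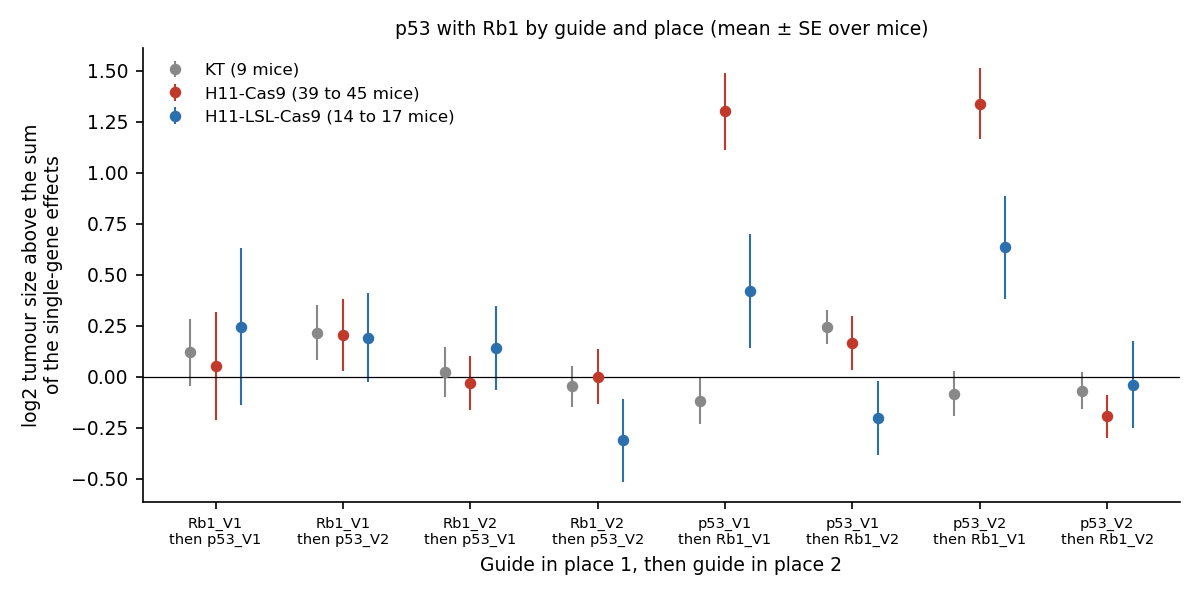
Log2 tumour size above the sum of the single-gene effects for each order and guide of p53 with Rb1, mean and standard error over mice, in KT, H11-Cas9 and H11-LSL-Cas9. In H11-Cas9 the arrangements p53_V1 then Rb1_V1 and p53_V2 then Rb1_V1 lie at 1.30 and 1.34, and the other 6 lie between -0.19 and 0.21.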

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

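The tests of same-guide constructs, of the p53 with Rb1 arrangement, of p53 guides by place and of the spike-in total were chosen after the result was seen. Those of Rb1 guide V1 by place, of reads per cell and of a common editing share were chosen before it. Of 41 measures tested in the 9 KT mice, 7 had a mouse far from the others by Dixon's test at the 95% level, where chance gives about 1 in 20. KT mouse 2 had 11053 tumours of at least 1000 cells (others 1594 to 4626) and 3.89e+07 tumour cells in all (others 8.96e+06 to 1.64e+07). Kmt2a tumours lay at -0.56 log2 units of inert/inert in KT mouse 7 (others 0.03 to 0.41), Rasa1 tumours at 0.37 in KT mouse 5 (others -0.17 to 0.09) and Rb1 tumours at 0.35 in KT mouse 6 (others -0.12 to 0.09). In number over inert/inert, Meaf6 lay at -2.85 in KT mouse 6 (others -2.38 to -1.91) and Nf1 at 1.33 in KT mouse 1 (others 0.99 to 1.14). No explanation was tested for these mice. Outside the tumours, 65 spike-in entries had under 5000 cells, the largest 794.6, in 48 mice, and 1 entry joined a spike-in with a guide.

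Constructs with the same guide in both places drew notice as data left aside, with 6757 tumours over all mice. In KT mice, where the guides cannot cut, there were 4170 such tumours of 32 guides, a median of 0.491 of the number expected from how often each guide was seen in each place (0.292 to 0.938). They were smaller than other tumours of the same guide for 31 of 32 guides, by a median of -0.74 log2 units. They made up 32.1% of the inert/inert tumours (692 of 2158), so they lowered the reference of every contrast. With them, single genes in KT lay at a median of 0.131 above inert/inert, and without them at 0.0440, so the smaller same-guide tumours may account for most of the excess. Whether the difference arises only among the smallest tumours stayed open, since same-guide inert tumours lay at -0.27 ± 0.08 in all sizes and at -0.12 ± 0.06 among tumours of at least 200 cells, close to 2 standard errors from 0. The bounds of that test were first 2 standard errors on either side and were changed to 1 and 2, with an undecided range between, after the value was seen. No biological explanation was tested, and loss of a repeated stretch in the virus or reads that join different molecules cannot be checked from these data.

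The size of p53 with Rb1 tumours differed between the Cas9 groups, and Rasa1 was the gene that did so, by a test of the difference between groups. Rasa1 tumours were larger in H11-Cas9 by 0.35 (0.25 ± 0.04 against -0.10), and so were 4 of 98 pairs. The excess of p53 with Rb1 over the product of its single effects, 0.49 in H11-Cas9, was 0.0043 ± 0.07 without constructs with p53 in place 1 and the Rb1 guide V1 in place 2. These are the 2 highest of 8 arrangements, and leaving out the highest lowers the value by itself, so the test first used, that this value lay within 2 SE of 0, was replaced after it was seen. With arrangements permuted among the tumours of each mouse and the 2 highest taken anew, it stayed at or above 0.33 (permutation p = 0.0001, the smallest that 10000 permutations can give). With the 2 chosen in part of the mice, they were the same in 100 of 100 random draws, and the excess without them in the remaining mice had a median of 0.0036 (SE 0.10). With all arrangements and 1 mouse left out at a time the excess ranged from 0.46 to 0.52. An equally large size effect of Rb1 guide V1 in place 2 beside any partner was excluded. Over 14 other partners the difference was 0.10 ± 0.06 against 1.31 beside p53 (10 above 0, 0 passing the sign-flip test, 0 at an unadjusted p under 0.05). An equally large size effect of p53 in place 1 was excluded too, at 0.00996 ± 0.07 over 15 other partners (9 above 0) against 0.71 beside Rb1. That mean weights partners equally and is lowered by partners of few mice (Kmt2b -0.54 ± 0.48, 9 mice, and Pcna -0.63 ± 0.39, 8 mice). Both tests read size, which Rb1 and p53 beside an inert guide moved by only 0.15 and 0.29. Stronger cutting that shows in size mainly beside the other gene is therefore not excluded by them. Still, 3 of the 15 p53 partners passed the sign-flip test when adjusted over the p53 partners alone (Keap1 0.34, Rnf43 0.26, inert 0.14). Of these, Rnf43 alone passed when all orders were adjusted together, so a smaller effect of place may exist. The test of p53 by place took the position of a planned test of a single mouse, which the range above excludes. An effect of the guides in this arrangement remains a candidate explanation. In H11-LSL-Cas9, where it was not chosen, it lay at 0.49 ± 0.20 (15 mice, permutation p = 0.0308), but at 0.66 ± 0.42 among tumours of at least 200 cells (10 mice, p = 0.154), and neither of its 2 guide combinations passed (adjusted p = 0.41 and 0.162). The loss of both proteins was not measured, so a biological synergy stays untested.

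Tumour numbers differed between the Cas9 groups for 6 genes by permutation of the mice, Apc (-0.45), Keap1 (-0.50), Kmt2b (-0.47), Lkb1 (-0.80), Meaf6 (-0.59) and Pcna (-2.47), and for 59 of 136 pairs, each lower in H11-Cas9. The median difference of these 65 genotypes, -0.79, was -0.65 among mice with the spike-in total near 300000 cells, where all 65 lay below 0 and 43 were called again, Meaf6 (-0.35) and Kmt2b (-0.23) not among them. These 65 were chosen over mice that include those, so their signs are not an independent check. Over all 153 genotypes, without that choice, the median was -0.30 near 300000 cells and -0.37 in all mice. Of the 153, 44 were called lower and 3 higher near 300000 cells. The spike-in total therefore did not account for the whole difference. Fewer reads per cell did not account for the whole either. The same chosen 65 had a median of -0.64 among tumours of at least 200 cells (62 below 0, 31 called again). If a fixed share of H11-LSL-Cas9 tumours were edited as in H11-Cas9, every gene that fell would give the same share. Instead, from summed tumours, Pcna gave 73.1% (95% interval 68.2 to 77.7), Keap1 61.0% (42.3 to 76.1), Lkb1 42.4% (25.2 to 57.2), Kmt2b 67.4% (33.9 to 96.0), Apc 42.2% (10.7 to 69.5) and Setd2 42.04% (-15.8 to 91.0). These differed by more than resampling of the mice allows (p = 0.0055), and of all intervals only those of Pcna and Lkb1 do not overlap, so Kmt2b, Apc and Setd2 bear little on it. From the mean log2 ratios over mice Pcna gave 73.3%, Keap1 57.4% and Lkb1 41.98% (p = 0.0095). That argues against a share common to all genes and leaves shares that differ by guide, later cutting, viral dose and the allele itself open. The 2 groups also share no letters in their mouse names, so a batch marked by these cannot be told apart from the allele, and the genotype may be the cause but was not separated from any of them.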

How the results depend on the processing

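Settings named here as added were chosen after the data were seen, and the cause was not tested for any change given below unless stated. Around the reported values of the named genes and pairs, settings of a kind added after the data were seen left 384 values with the same direction and side of the threshold, while 63 no longer passed, 24 came to pass and 2 changed sign. Under kinds fixed beforehand (90th percentile, adaptive sampling, weighted mice and summed numbers) these were 133, 14, 9 and 11, the 11 all under adaptive sampling. The minimum of 1000 cells, fixed beforehand too, is not among these kinds. There 21 values kept direction and side of the threshold, 11 no longer passed, 3 came to pass and 10 changed sign. In H11-Cas9, size over the 10 settings other than 1000 cells kept its side in all 10 for Nf1 (0.32 to 1.12), p53 (0.20 to 0.67), Rasa1 (0.19 to 0.61), Nf1 with p53 (0.46 to 1.47) and p53 with Rb1 (0.89 to 2.34). Pcna size kept its side in 4 of 9 (-1.39 to -0.25) and Ccnl1 in 5 of 10 (0.06 to 0.34). Of the size interactions, Ccnl1 with Nf1 kept its side in 4 of 9 (-1.07 to -0.035) and Ccnl1 with p53 in 5 of 10 (-1.26 to 0.078). Ccnl2 with Setd2 did so in 4 of 10 (-0.93 to 0.18), Keap1 with Nf1 in 8 of 10 (-0.94 to -0.26). For p53 with Rb1 it was 9 of 11 (0.0043 to 1.35). In number Pcna (-4.78 to -3.71), Lkb1 (-1.44 to -1.07), Keap1 (-1.39 to -0.84), Kmt2b (-1.39 to -0.82) and Apc (-0.96 to -0.64) kept theirs in 8 of 8, again without 1000 cells. At 1000 cells Pcna passed in number (-2.99). Lkb1 (-0.20), Keap1 (-0.65), Apc (-0.05) and Kmt2b (0.24) did not pass the label permutation there. In size 0 single genes and 0 pairs passed there, over at most 3 mice. Depth limits tumours near 50.1 cells, and few tumours limit Pcna, Meaf6, Kmt2b, Kat7 and Ccnl1.

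Around the planned minimum of 1000 cells, a minimum of 500 cells gave in H11-Cas9 5 single genes in size, 19 pairs, 14 steps and 1 guide contrast (0, 0, 3 and 0 at 1000 cells, with more mice to test). In H11-LSL-Cas9 it gave 4 steps, 1 single gene in number, 51 pairs in number (43 up, 8 down) and 6 number interactions (0, 6, 86 and 0 at 1000 cells). A minimum of 2000 cells gave in H11-Cas9 0 steps by the sign-flip test (2 at an unadjusted p under 0.05), 4 single genes in number and 10 number interactions, and in H11-LSL-Cas9 2 number interactions. No minimum gave in H11-Cas9 13 single genes, 50 pairs, 42 size interactions, 41 steps, 11 single genes in number and 9 number interactions. In H11-LSL-Cas9 it gave 1 single gene, 10 pairs, 7 steps, 2 single genes in number and 22 pairs in number, and in KT 3 single genes. It also moved summed cells per mouse to -1.14 and -2.71, past the threshold, and turned inert/inert size to -0.71 and -0.56. Without H11-LSL-Cas9 mice 3 and 7, of under 20 tumours, an added setting, summed cells came to pass at 1000 cells (-1.09) and passed with no minimum (-1.71), and inert/inert size stayed at -0.56 there. With no minimum and either of the 2 left out, summed cells lay at -2.32 and -2.15 and inert/inert size at -0.56. At least 10 tumours left 1 step. Summed numbers gave in H11-Cas9 0 single genes by permutation (4 unadjusted), 7 pairs and 0 interactions (8 unadjusted). A pseudocount of 1 gave 25 and 3 number interactions. Relative to all tumours, H11-LSL-Cas9 had 1 single gene and 52 pairs in number. Leaving out each KT mouse gave 0 to 1 number interactions in H11-LSL-Cas9. With 1000 cells no genotype could be tested for size in either Cas9 group at 2000 cells, with adaptive sampling or with at least 10 tumours, for steps with adaptive sampling, nor in H11-LSL-Cas9 with the 90th percentile, weighted mice, log2 of the mean size or log2 burden, so these give no value. No paired analysis was possible because the replicate numbers follow the order of the labels and no source used here pairs mice across groups.

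Around the reported values, keeping same-guide constructs gave in H11-Cas9 42 size interactions (23 reported) and 11 single genes in number (7), and in H11-LSL-Cas9 1 single gene (2) and 10 pairs (4) in size. A minimum of 200 cells gave in H11-Cas9 19 number interactions (10). In H11-LSL-Cas9 it gave 1 single gene and 19 pairs in size, 8 single genes in number (4), 6 number interactions (0) and 1 guide contrast (4), and between the Cas9 groups 1 genotype in size (5) and 33 in number (65). The spike-in total near 100000 cells, with fewer mice, gave in H11-Cas9 12 size interactions, 16 steps (39) and 48 pairs in number (75). The total near 300000 cells gave 5 single genes (12), 22 pairs (39), 4 interactions and 8 steps in size and 1 number interaction, as did the same total with names beginning with LA. It gave in H11-LSL-Cas9 against fewer KT mice 1 single gene and 11 pairs in number (33), and between the Cas9 groups 1 genotype in size. Set against KT, H11-Cas9 had 5 single genes and 2 interactions in size, and H11-LSL-Cas9 2 pairs. Adaptive sampling gave 73 steps in H11-Cas9, and 25 pairs and 36 steps (7) in H11-LSL-Cas9. In H11-LSL-Cas9 the 90th percentile gave 1 single gene and 12 steps, at least 10 tumours 1 single gene and 12 pairs, and weighted mice 10 pairs. Counting NE as inert gave 11 single genes in number in H11-Cas9 and 9 pairs in size in H11-LSL-Cas9. The studentised permutation gave in number 13 single genes and 17 interactions in H11-Cas9 and 55 pairs in H11-LSL-Cas9. A pseudocount of 1 gave 21 and 1 number interactions. Relative to all tumours, H11-Cas9 had 12 single genes in number and H11-LSL-Cas9 7 single genes and 52 pairs. Summed numbers gave in H11-Cas9 17 pairs and 0 interactions by permutation (3 unadjusted), and in H11-LSL-Cas9 11 single genes and 76 pairs. Without a minimum of inert/inert tumours, H11-LSL-Cas9 had 2 single genes, 20 pairs and 1 interaction in number. Leaving out each KT mouse gave 2 to 4 single genes in number in H11-LSL-Cas9, the 2 without KT replicate 1, 4, 6, 7 or 8, and 5 to 7 in H11-Cas9 (7).

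Signs turned under adaptive sampling, which counts tumours that are missing as small, for Apc (-0.47), Kat7 (-0.58), Keap1 (-0.81), Lkb1 (-0.61), Setd2 (-0.0074), Apc with Lkb1 (-0.26), Lkb1 with Setd2 (-0.38), Apc with Rasa1 (-0.057) and Lkb1 with Rnf43 (-0.63) in size and for the interactions of Ccnl1 with p53 (0.078) and Ccnl2 with Setd2 (0.18). With the spike-in total near 300000 cells Apc lay at -0.0049 and Lkb1 with Setd2 at -0.023. At 1000 cells Rnf43 size lay at -0.29, and number turned in H11-Cas9 for Ccnl1 (1.34), Kmt2b (0.24), Meaf6 (1.56), Setd2 (0.21) and the interaction of Ccnl1 with Ccnl2 (0.071), and in H11-LSL-Cas9 for Ccnl1 (1.496), Kat7 (1.48), Kmt2a (1.41) and Lkb1 (0.069). The cause was not tested.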

Other observations

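Mice were split at random into groups of the real sizes 100 times, the real split included, to ask how often chance gives as many calls. The splits were fixed before the result was seen, and their number of resamples was chosen after it. For single genes in number, 1 split of H11-Cas9 against KT gave as many as the 7 calls (highest other 2) and 3 splits of H11-LSL-Cas9 gave as many as its 4 (highest other 9). For pairs in number, 1 split gave as many as the 75 of H11-Cas9 (highest other 6) and 2 as many as the 33 of H11-LSL-Cas9 (highest other 34). For number interactions, 1 split gave as many as the 10 of H11-Cas9 (highest other 3), while with 0 calls in H11-LSL-Cas9 all 100 splits gave as many (highest other 22). In size minus KT, 1 split gave as many as the 5 single genes of H11-Cas9 (highest other 1), 1 as many as the 2 of H11-LSL-Cas9 (highest other 1). There, 1 gave as many as the 26 pairs of H11-Cas9 (highest other 4) and 3 as many as the 2 pairs of H11-LSL-Cas9 (highest other 4). For size interactions minus KT, 1 split gave as many as the 2 of H11-Cas9 (highest other 1), and with 0 in H11-LSL-Cas9 all 100 did (highest other 2). Between the Cas9 groups, 2 splits gave as many as the 5 genotypes in size (highest other 6) and 1 as many as the 64 in number (highest other 8). For the counts above 0 fewer than 5 in 100 splits gave as many, but the counts were not adjusted for each other. With 100 splits, a count reached by 2 or 3 of them cannot be told firmly from 5 in 100. Chance is thus not excluded for the single genes and pairs in number of H11-LSL-Cas9. Nor is it for its 2 size pairs or the size differences between the Cas9 groups. For the remaining counts above 0 only the real split gave as many. Some splits of H11-LSL-Cas9 and KT mice called more in number than the real one, up to 34 pairs or 22 interactions. All number contrasts of a mouse share its inert/inert count, so their calls are not independent, and what these splits have in common was not tested. These splits used 20000 resamples each, so the real count of 64 differs from the 65 given above, and with 5000 resamples, the number first used, the 2 pairs of H11-LSL-Cas9 in size were 0, so that count was not relied on.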
